A study of Mus musculus with 11 samples.

How the data were processed

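Total RNA of back skin was measured in 11 samples, 7 with tdTomato-negative and 4 with tdTomato-positive donor marrow, as the labels give them. Per the labels' protocols, libraries were made with a total RNA kit that removes ribosomal RNA with RNase H and were sequenced on a NextSeq2000. The submitters' processing notes name bcl2fastq, Trim Galore, RSEM and the GRCm38 build. The versions, the aligner and the strand setting are not given in the sources used here.

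The deposited values are RSEM estimates per gene, 1 file per sample, per the file headers. The expected counts deposited by the authors are estimated read counts, not normalized, in which RSEM divides reads that map to several genes between them. About 8% of genes per sample had expected counts further than 0.005 from a whole number. The TPM values deposited by the authors are relative to the effective length of each gene and sum to the same total in each sample. The effective lengths deposited by the authors were used for a length offset. The FPKM column was not used. Genes that share reads with near-identical copies have uncertain counts, and which genes these are was not tested.

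Expected counts were rounded to whole numbers and used for the tests. Totals ranged from 7190750 to 9749840 per sample, and a count of 0 in a sample allows up to 3 counts. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. Of 24411 genes in the files, 14588 passed the filterByExpr filter of edgeR (minimum count 10, minimum total 15). Samples were scaled with TMM factors, and CPM were computed with the TMM-scaled totals of the tested genes. The test was edgeR 4.0.16 glmQLFit and glmQLFTest with group as the only term, positive minus negative, with Benjamini-Hochberg adjusted p under 0.05 (R 4.3.3). In this test glmQLFit ran in its legacy mode, without the version 4 deviances. Standard errors are the log2 fold change divided by the square root of the F value, and intervals hold 95%.

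Gene lists for the model, the tissue and its possible cell types were fixed before the data were examined, 33 in all, with 727 distinct symbols, of which 697 were found in the files. The 30 symbols not found included Flg, Ly6g and the constant regions of T cell receptors and immunoglobulins. A list needed 5 tested members. The mitochondrially encoded list had 0 members in the files, and the sex-linked list served as a check of the samples only, which left 31 tested lists. There were 27 symbols in more than 1 list. Lists were tested with camera (limma 3.58.1) with the correlation between genes estimated for each list, with Benjamini-Hochberg adjustment over the 31 lists. Beside it stand camera with a preset correlation of 0.01, fry, and an exact permutation test over all 330 splits of the mean z-score per sample. A list score is that mean z-score of log2 CPM.

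The rule for named genes was also fixed beforehand. It took Pdgfra, the genes past the threshold or, where fewer than 5 passed in a direction, those with the smallest p up to 5, and 3 members each of the type 2 inflammation, leukocyte extravasation and barrier lists. It skipped predicted and sex-linked genes. Coordinates are those of RefSeq on GRCm38.p6.

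Alternatives planned before the data were examined were other normalizations and filters, DESeq2 1.42.0, voom with and without sample quality weights, limma-trend on log2(TPM + 1), effective-length offsets, covariates for hair, muscle and adipocyte scores, 1 surrogate variable (sva 3.50.0), a replicate block and leaving out each sample. A sex term was not run, since Xist was high and Y-linked counts were near 0 in all 11 samples. DESeq2 left 1981 adjusted p-values as NA, and these stayed out of its counts. No library was a copy of another: over pairs of samples the chi-square per degree of freedom was never below 3.78.

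The tests were run on simulated counts for the real genes, drawn from the means, library sizes and dispersions of the samples, with 200 genes changed by 1.5-fold, 2-fold or 4-fold. Of the 14468 genes that passed the filter there, edgeR recovered 31.3%, 70.1% and 97.0% of genes changed by these folds, with 3 false calls among 135. DESeq2 made 33 false calls among 185, voom 4 among 129 and quality-weighted voom 4 among 128. With no gene changed, DESeq2 called 6 genes and the other 3 called 0. The means, library sizes and dispersions hold no correlation between genes. The false calls here therefore do not cover a structure shared by the real samples. Among the other splits of the real samples that were run, the most genes called were 2250 with quality-weighted voom, 1813 with edgeR and 1469 with DESeq2.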

Results

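Gene expression was measured by total RNA sequencing of mouse back skin with dermatitis induced by MC903 (calcipotriol), a vitamin D analog that produces a skin inflammation used as a model of atopic dermatitis. The hosts carried a ubiquitous EGFP transgene, were irradiated with 10 Gy and received sorted femoral marrow cells of Pdgfra-Cre;tdTomato donors, in which tdTomato marks cells whose lineage has expressed Pdgfra. In 7 samples the donor cells were tdTomato-negative and in 4 samples tdTomato-positive. MC903 was applied 6 times after a recovery of 6 weeks, and skin was taken on day 14. Expected counts summed to between 7190750 and 9749840 per sample, with 8163570 ± 1104130 (SD, n = 4) in the positive and 7835300 ± 557167 (SD, n = 7) in the negative group (two-sided exact permutation p = 0.536). The labels number the samples without stating that each came from its own animal, so p-values measure the spread between these samples.

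The comparison asked how skin with dermatitis differed when the transplanted marrow came from the PDGFRα lineage. Skin of the tdTomato-positive group had lower mean levels of hair follicle and pigment cell transcripts and higher mean levels of macrophage, vascular, fibroblast and muscle transcripts than skin of the tdTomato-negative group. None of these gene groups passed camera with an estimated correlation, and none of their genes passed edgeR's test over all genes. All 35 hair shaft and follicle genes had a fitted log2 fold change (positive minus negative) below 0, with a median of -2.27. The macrophage and monocyte list had a median of 0.58, with 25 of 26 tested members above 0. Its score was high in positive replicates 1 and 2 only (1.75 and 1.10). In positive replicates 3 and 4 it was -0.557 and -0.245, within the -1.03 to 0.22 of the negative group.

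Of 14588 genes tested with edgeR's quasi-likelihood test, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.248. At an unadjusted p under 0.05 there were 2448 genes, 1029 higher and 1419 lower in the positive group, where 729 would be expected with no difference. The groups did not overlap in 244 genes, where 88 (0.606%) would be expected by chance. How widely this number varies between splits of the samples was not tested, so it shows no excess beyond chance. The 2448 genes at an unadjusted p under 0.05 were reached by 6 of 100 splits, the real one included. The highest other split had 4211, so chance cannot be excluded for that count. Other tools differed: limma-voom called 0 genes, DESeq2 83 (43 higher, 40 lower) and limma-voom with sample quality weights 2093 (982 higher, 1111 lower). With the hair list score as a covariate, the edgeR test called 0 genes and 1077 had an unadjusted p under 0.05.

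Pdgfra, the receptor gene whose lineage marked the donor cells and a gene of dermal fibroblasts, stood at 166 ± 32.6 CPM (SD, n = 4) in the positive and 123 ± 19.8 CPM (SD, n = 7) in the negative group. Its log2 fold change was 0.43 ± 0.14 (SE), with an edgeR adjusted p of 0.248, and the groups overlapped. On GRCm38.p6 the gene lies on chromosome 5 from 75151322 to 75198206. These libraries hold RNA of the whole skin, in which host fibroblasts also express Pdgfra.

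The 5 genes with the smallest p among those higher in the positive group did not pass the adjusted threshold. Fli1, an ETS transcription factor of endothelial and blood cells, had 29.0 ± 3.96 CPM (SD, n = 4) against 17.1 ± 3.02 CPM (SD, n = 7), a log2 fold change of 0.76 ± 0.14 (SE). Abcd2, a peroxisomal transporter of very long chain fatty acids, had 37.6 ± 3.76 against 23.3 ± 3.97 CPM. Ghr, the growth hormone receptor, had 115 ± 20.1 against 82.1 ± 2.28 CPM, and its 7 negative samples lay between 78.5 and 84.3 CPM. Zc3h6, a zinc finger gene, and Phf20, a chromatin reader, had log2 fold changes of 0.64 and 0.42. In all 5 genes each positive sample lay above each negative sample. Choosing genes by the smallest p in these same samples favors such a separation, so it is no further support. Fli1 lies on chromosome 9 (32422204 to 32543432), Abcd2 and Ghr on chromosome 15 (91145871 to 91192007 and 3317755 to 3583352), and Zc3h6 and Phf20 on chromosome 2.

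The 5 genes with the smallest p among those lower in the positive group did not pass either. In each the groups did not overlap, which the choice by p again favors. Nrarp, a feedback inhibitor of Notch signaling, had the smallest p of all tested genes, at 54.8 ± 5.71 CPM (SD, n = 4) against 83.5 ± 8.08 CPM (SD, n = 7). Its log2 fold change was -0.61 ± 0.09 (SE), with an edgeR adjusted p of 0.248, and it lies on chromosome 2 from 25180758 to 25183339. Nrarp moved with hair content within the groups. It had 70.4 and 76.2 CPM in negative replicates 1 and 7, whose hair scores were below 0. The other negative samples had 83.7 to 95.3 CPM. In positive replicate 4, whose hair score was above 0, it had 60.8 CPM, against 49.7 to 58.7 CPM in the other positive samples. Amotl2, an angiomotin family gene of cell junctions, had 67.0 ± 5.26 against 90.3 ± 8.71 CPM. Ip6k2, an inositol hexakisphosphate kinase, had a log2 fold change of -0.45 ± 0.09 (SE). The methyltransferase genes Ntmt1 and Trmt61a, for protein N termini and transfer RNA, had log2 fold changes of -0.58 and -0.66. Of the 20 named genes, DESeq2 called 11 and quality-weighted voom all 20. With the hair score as a covariate, in fits chosen after the results were seen, DESeq2 called 2 genes in all (Ghr and Nrarp) and quality-weighted voom 0.

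**Figure D1:**
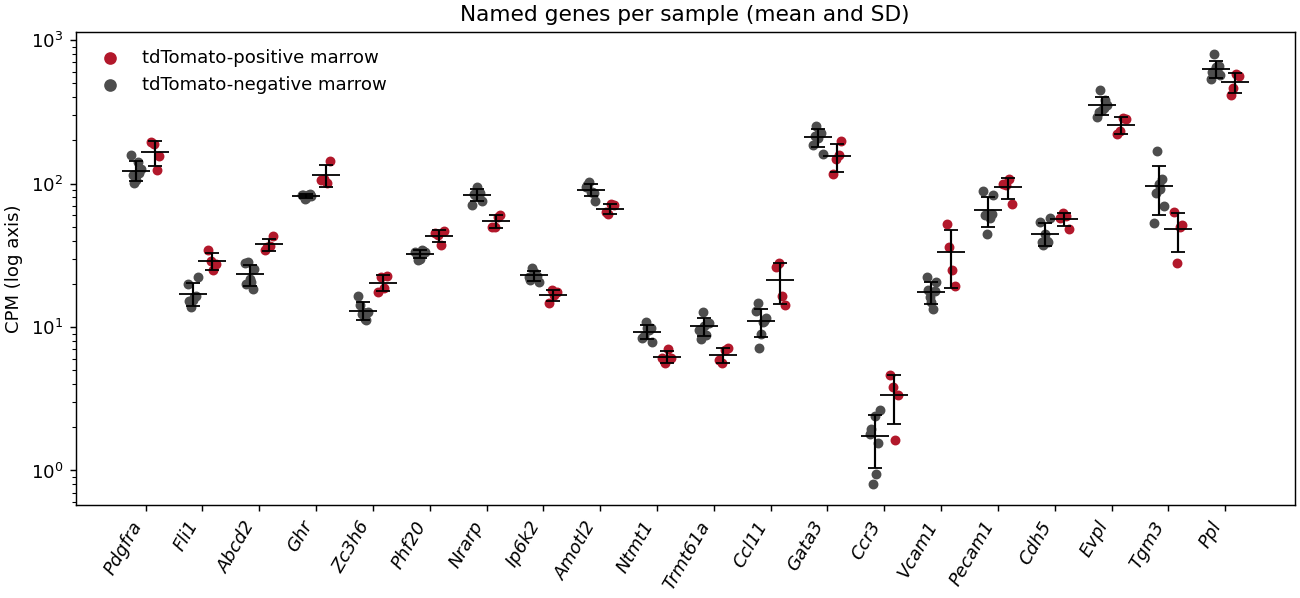
CPM of the 20 named genes (log axis) in each sample, negative group in grey (n = 7) and positive group in red (n = 4), with the mean and SD of each group as bars. Ghr spans 78.5 to 84.3 CPM in the 7 negative samples, all below the 4 positive samples.

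In the type 2 inflammation list, which holds the cytokines and chemokines of allergic responses, 18 of 21 tested members had a log2 fold change above 0, with a median of 0.38. With edgeR, none of them passed over all genes and 1, Ccl11, passed adjusted over the list alone. Ccl11, the eosinophil attractant eotaxin, had 21.2 ± 6.84 CPM (SD, n = 4) in the positive group, with a log2 fold change of 0.95 ± 0.22 (SE). It lay between 7.14 and 14.6 CPM in the 7 negative samples. In positive replicates 1 to 4 it had 26.3, 27.9, 16.4 and 14.3 CPM, so the groups overlapped. Ccr3, its receptor, had 3.37 ± 1.26 against 1.73 ± 0.69 CPM, at low counts. Gata3, a transcription factor of type 2 lymphocytes that is also expressed in hair follicle and epidermis, had 155 ± 33.9 against 210 ± 29.2 CPM. Gata3 moved with hair content within the groups. It had 186 and 160 CPM in negative replicates 1 and 7, whose hair scores were below 0, and 208 to 250 CPM in the other negative samples. In positive replicate 4, whose hair score was above 0, it had 199 CPM, against 117 to 157 CPM in the other positive samples. Camera called the list with the preset correlation (adjusted p = 0.0112) and not with an estimated correlation (adjusted p = 0.426). Without positive replicate 1 its median was 0.17.

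Leukocyte extravasation, the subject named in the study's title, was tested with a list of adhesion molecules, selectins and endothelial junction genes. Of its 26 tested members, 22 had a log2 fold change above 0, the median was 0.33, and 10 had an unadjusted p under 0.05 in that direction. With edgeR, none passed over all genes and 1, Vcam1, passed adjusted over the list alone. Vcam1, the endothelial ligand of leukocyte integrins, had 33.1 ± 14.4 CPM (SD, n = 4) against 17.6 ± 3.12 CPM (SD, n = 7). It had 52.0, 36.2, 25.1 and 19.3 CPM in positive replicates 1 to 4. The negative samples reached 22.4 CPM, so the groups overlapped. Pecam1 and Cdh5, both endothelial junction genes, had 94.0 ± 15.4 against 65.0 ± 15.2 CPM and 56.7 ± 6.04 against 44.6 ± 8.10 CPM. Both moved opposite to hair content within the groups, higher where hair scores were lower. Pecam1 had 88.4 and 82.8 CPM in negative replicates 1 and 7, whose hair scores were below 0, and 44.7 to 61.3 CPM in the other 5. It had 71.7 CPM in positive replicate 4, whose hair score was above 0, and 97.6 to 107 CPM in the other 3. Cdh5 had 54.2 and 57.7 CPM in negative replicates 1 and 7, 37.3 to 44.7 CPM in the other 5, 48.2 CPM in positive replicate 4 and 57.2 to 62.3 CPM in the other 3. With the hair score as a covariate, the log2 fold changes were 0.25 for Pecam1 and 0.13 for Cdh5, and the median of the list was 0.22. The list's adjusted p was 6.11e-05 with the preset correlation and 0.426 with an estimated correlation. Without positive replicate 1 its median was 0.17.

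In the epidermal differentiation and barrier list, 20 of 29 tested members lay above 0 and 9 below, with a median of 0.18, and with edgeR 0 passed over all genes or adjusted over the list alone. The members with the smallest p lay below 0. Evpl (envoplakin) and Ppl (periplakin), scaffold proteins of the cornified envelope, had 256 ± 33.4 against 351 ± 51.4 CPM and 507 ± 81.1 against 634 ± 85.8 CPM. Tgm3, a transglutaminase of epidermis and hair follicle, had 47.9 ± 14.6 against 96.4 ± 36.4 CPM. It had 53.4 and 69.4 CPM in negative replicates 1 and 7, whose hair scores were below 0, and 85.3 to 168 CPM in the other negative samples. In positive replicate 4, whose hair score was above 0, it had 51.1 CPM, within the 28.0 to 63.2 CPM of the other positive samples. Camera did not call the list, with adjusted p = 0.706 with an estimated correlation. Its median was 0.02 without positive replicate 3, 0.27 without negative replicate 7 and -0.11 with the hair score as a covariate.

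The leukocyte lists had medians above 0, and with edgeR 0 members of any of them passed over all genes. The median log2 fold change was 0.84 for neutrophils (all 16 tested members above 0), 0.58 for macrophages and monocytes, 0.36 for T cells (24 of 27), 0.53 for NK and cytotoxic lymphocytes (7 of 7), 0.61 for eosinophils (4 of 5) and 0.50 for B and plasma cells (4 of 6). The type I interferon response list had a median of 0.53 with 21 of 22 members above 0. For type 17 inflammation, the type 1 and interferon-gamma response and immune regulation the medians were 0.60, 0.28 and 0.25. Camera with the preset correlation called these lists except eosinophils and B and plasma cells. With an estimated correlation the adjusted p of the neutrophil and type I interferon lists was 0.522, that of the macrophage, T cell and NK lists 0.426, that of the type 17 and immune regulation lists 0.514 and that of the type 1 list 0.533. Much of these medians rested on positive replicate 1: without it they were 0.16 for neutrophils, 0.30 for macrophages, 0.22 for B and plasma cells, 0.10 for type I interferon, 0.13 for type 17, 0.08 for type 1 and 0.02 for immune regulation. The neutrophil median was 1.27 without positive replicate 3, the NK median 0.98 without negative replicate 1 and the type 1 median 0.43 without positive replicate 4. With the hair score as a covariate, the medians were 0.38 for macrophages, 0.35 for eosinophils, 0.81 for neutrophils and 0.54 for NK cells. They were 0.34 for T cells, 0.40 for B and plasma cells, 0.42 for type I interferon, 0.45 for type 17, 0.32 for type 1 and 0.20 for immune regulation.

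Hair follicle and pigment cell genes differed by the largest medians among the 31 tested lists. Hair list genes took 0.698 ± 0.754% of the expected counts (SD, n = 4) in the positive and 2.90 ± 1.91% (SD, n = 7) in the negative group (two-sided exact permutation p = 0.0606). Single samples ranged from 0.199% to 5.48%, and both of these were negative samples. Trichohyalin (Tchh) and Krt71, inner root sheath genes looked at as markers of growing hair, had 2518 ± 3337 against 12612 ± 8797 CPM and 853 ± 1191 against 4421 ± 3101 CPM. The hair list had an adjusted p of 9.22e-08 with the preset correlation and 0.474 with an estimated correlation of 0.869 between its genes, and its median was -4.12 without positive replicate 4. The melanocyte list had a median of -1.47, with 13 of 14 tested members below 0 and 6 that fell adjusted over the list alone. Among these, named after their values were seen, the melanin synthesis genes Tyrp1 and Dct had 9.43 ± 4.03 against 27.0 ± 14.4 CPM and 13.9 ± 6.40 against 37.6 ± 17.7 CPM. The melanocyte list had an adjusted p of 5.08e-05 with the preset correlation and 0.426 with an estimated correlation. With the hair score as a covariate, its median was -0.68.

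**Figure D2:**
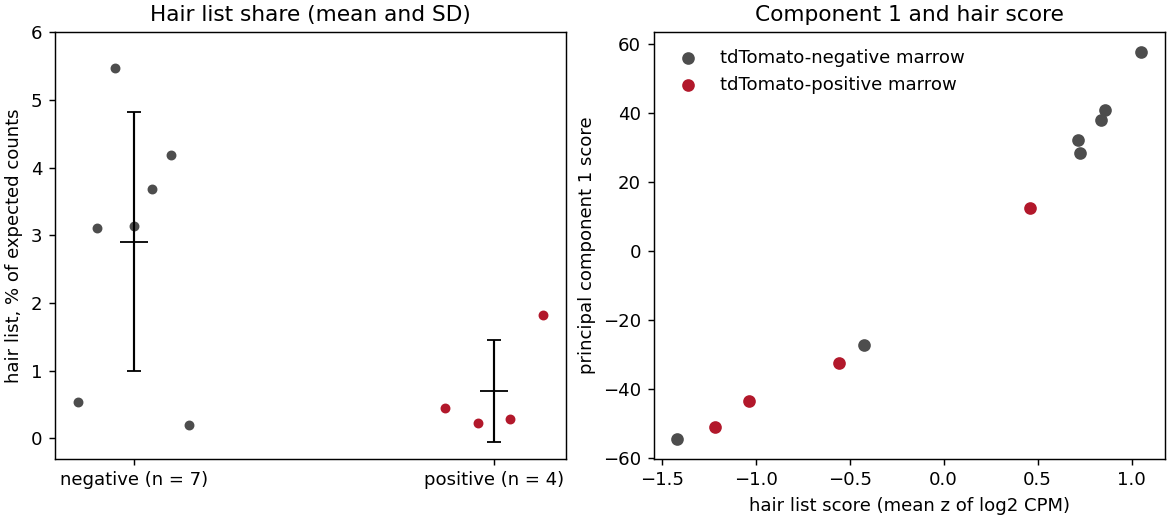
Left, the percent of expected counts in the 35 hair list genes in each sample, with the mean and SD of each group (7 negative, 4 positive). Right, the score of each sample on the first principal component of log2 CPM against its hair list score (mean z of log2 CPM), which follow each other over both groups with r = 0.988.

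The first principal component held 56.3% of the variance between the 11 samples, and 37 of the 50 genes with the largest loadings were hair genes. Tissue lists also had medians above 0: 0.32 for fibroblast and extracellular matrix (29 of 30 members), 0.32 for endothelium and pericyte (20 of 23) and 0.40 for skeletal muscle (24 of 24). All 3 were called with the preset correlation and had adjusted p = 0.426 with an estimated correlation. The endothelial and fibroblast scores moved opposite to the hair score within the groups, higher where hair scores were lower. The endothelial score was 0.81 and 0.49 in negative replicates 1 and 7, -0.77 to -0.48 in the other 5, -0.01 in positive replicate 4 and 0.54 to 0.79 in the other 3. The fibroblast score was 0.71 and 0.18, -1.11 to -0.21, -0.14, and 0.11 to 1.14 in the same order. With the hair score as a covariate, the medians were 0.12 for endothelium and pericyte, 0.10 for fibroblast and extracellular matrix and 0.17 for skeletal muscle. The fibroblast median was 0.49 without negative replicate 1, and the muscle median was 0.24 without positive replicate 3 and 0.62 without negative replicate 7. Camera with the preset correlation called 20 of the 31 lists, 17 up and 3 down, and with an estimated correlation it called 0. Fry and the exact permutation test of list scores also called 0 lists. With 330 splits the permutation test can give no p below 0.00303, too large for 1 list alone to pass after adjustment over the 31 lists.

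**Figure D3:**
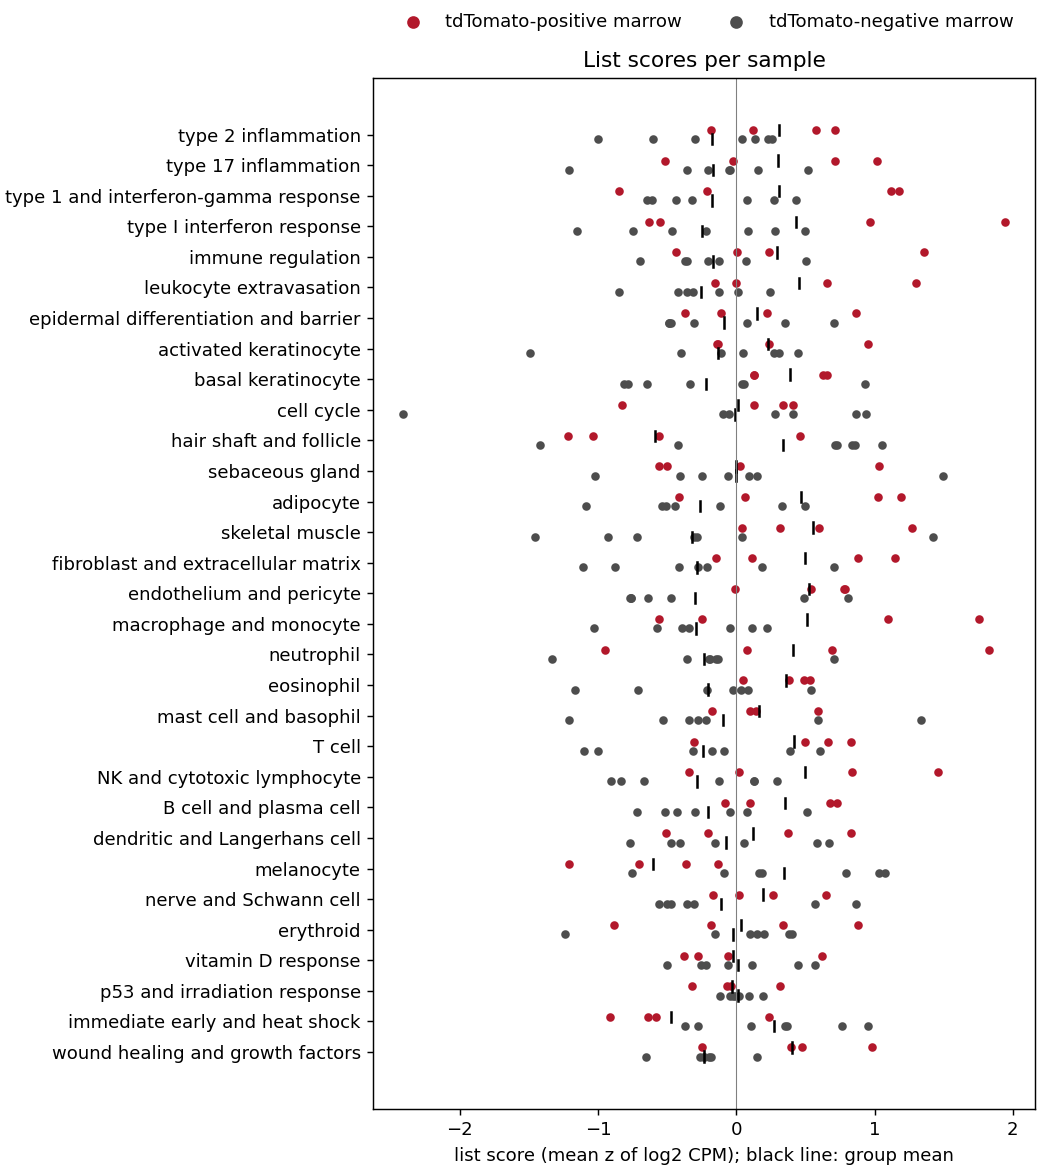
List scores (mean z of log2 CPM) of the 31 tested lists in each sample, negative group in grey (n = 7) and positive group in red (n = 4), with group means as black lines. Hair scores range from -1.42 to 1.05 within the negative group alone.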

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

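The tests of the hair cycle stage, of blood in the skin, of the vitamin D response and of the shared state of samples were chosen only after the results were seen. So were the splits for counts of 0, and the 2 fits of DESeq2 and quality-weighted voom with a hair covariate.

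A single value far from its group was found in 3 of 108 sets of values, where chance gives about 5. The cell cycle score of negative replicate 1 was -2.41, with the other 6 negative samples between -0.10 and 0.94. The erythroid score of the same sample was -1.24, against -0.15 to 0.40 in the others. Hair list genes took 1.82% of the counts in positive replicate 4 and 0.234% to 0.455% in the other positive samples. Reads of the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, which no comparison used, summed to 12 counts in negative replicate 1 and to 0 in the other 10 samples.

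Hair follicle genes had lower levels after tdTomato-positive marrow. Taking the hair genes out of the counts moved the median log2 fold change of the other genes by 0.0118, but scaling centres these genes, so this decides nothing about abundant genes taking the counts of others. With all libraries thinned to the smallest total, the hair list median stayed at -2.27, but fold changes are scaled to depth already, so this decides nothing about depth. An uneven hair cycle stage among few samples stays open, since the two-sided exact permutation p of the hair score was 0.103 and the groups overlapped. An effect of the donor marrow on the hair follicle also stays open and cannot be separated from it here.

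DESeq2 called 83 genes and quality-weighted voom 2093 where edgeR called 0, and 81 of the 83 were called by both. If the calls followed the hair genes, the hair covariate would bring the median ratio of adjusted to unadjusted fold changes under 0.5, and if not it would stay over 0.75. It was 0.800, on the second side, and the prediction named the median only. A stricter condition on the lower quartile, which the prediction did not hold, was not met, since the quartiles (0.672 and 0.923) span that bound. With the covariate DESeq2 called 2 genes (Ghr and Nrarp) and quality-weighted voom 0. In edgeR with the covariate, 83 of 83 kept their sign and 78 a p under 0.05. The 83 genes were picked by their difference in the same samples, so these signs and p-values cannot decide it. Whether the calls followed the hair genes stays open. The median ratio of tagwise to trended edgeR dispersion over the 83 genes was 0.551 (quartiles 0.355 and 1.10). Tagwise dispersions are already drawn toward the trend, so this ratio does not give the own dispersion of these genes. In a separate fit without the legacy mode, their own quasi-likelihood spread was 1.09 times the moderated one (quartiles 0.934 and 1.22). That fit was not the one used for the test, so whether edgeR widens the spread of these genes stays open.

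Macrophage and interferon scores were highest in positive replicates 1 and 2 (macrophage scores 1.75 and 1.10, interferon scores 1.94 and 0.970), and the other 9 samples lay below them. For blood in the skin piece, the erythroid score was -0.182 in positive replicate 1 and 0.339 in positive replicate 2. The summed hemoglobin CPM (of all counts), a measure added after the counts had been seen because RSEM can divide globin reads between copies, was 87.2 and 213, where the other 9 had a median of 107 and reached 271 in positive replicate 4, whose macrophage score was -0.245. For a stronger response to the vitamin D analog, its target Cyp24a1 had 282 CPM of all counts in positive replicate 1, the highest of the 11 samples, and 27.6 in positive replicate 2, below the median of 67.1 of the other 9. A first bound, 1 of the 2 samples below the median of the others, would exclude both explanations, but it was loosened to both samples after the values were seen, since 1 library decides little, and under that bound both stay open, as does an untested biological difference.

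Other splits of the 11 samples into 4 and 7 bear on the counts above 0. A count of 0, as edgeR gave for genes and camera with an estimated correlation for lists, is reached by all 100 of 100 splits by construction, so these say nothing about chance (highest others 1813 genes and 1 list). For edgeR genes at an unadjusted p under 0.05, 6 of 100 splits reached the real 2448 (highest other 4211), and with the hair covariate 12 of 60 reached 1077 (highest other 3416), so chance cannot be excluded. The same holds for DESeq2, with 5 of 60 splits at 83 genes or more (highest other 1469), and for lists with the preset correlation, with 5 of 100 at 20 lists or more (highest other 22). For quality-weighted voom 2 of 60 reached 2093 genes, the real split included (highest other 2250), a share under 0.05. These 60 did not include the drawn splits with 1813 and 406 edgeR calls, so chance cannot be excluded here either. The split with 1813 edgeR calls set negative replicates 1 and 7 and positive replicates 2 and 3, all with hair scores below 0, against the rest, and points to a structure of the samples. Its difference in hair score was -1.61, and the drawn split with the next largest difference, 1.36 (negative replicates 3, 4, 5 and 6), called 406 genes, but one with 1.32 called 0, and positive replicate 1, among the rest, also had a score below 0. Hair scores partly follow the groups, with 3 of 4 positive and 2 of 7 negative samples below 0.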

How the results depend on the processing

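The robust, version 4 and ribosomal RNA settings and all fits of DESeq2, voom or preset camera with a hair covariate were chosen after seeing the data. The count of changed genes was 0 in the edgeR fits with other scaling, filters, offsets or covariates, while DESeq2 gave 83, quality-weighted voom 2093 and DESeq2 with the hair score 2; the cause was not tested further. Leaving out each sample gave 0 to 3 genes. Without negative replicate 4 the gene was Amd1, and without negative replicate 7 the genes were Chrdl1 and Slc38a4 (higher) and Sccpdh (lower), all named after their values were seen. Amd1 had 0 counts in 6 negative samples, 661 in negative replicate 4, and 660, 332, 663 and 330 in positive replicates 1 to 4, with an exact permutation p of 0.0121 for its CPM. Whether reads were divided between Amd1 and Amd2 or a variant differs between the mice was not tested. The pair's summed CPM was 120 ± 13.5 (SD, n = 4) against 109 ± 16.2 (SD, n = 7), with an exact permutation p of 0.261. Genes at an unadjusted p under 0.05 numbered 2448, 1397 without positive replicate 1, 1337 without positive replicate 2, 1077 with the hair score and 1022 with 1 surrogate variable, against 3276 without negative replicate 1, 3338 without negative replicate 7, 2960 without positive replicate 4 and 5003 with quality-weighted voom. Correlations between samples of the same number were -0.04, -0.14, -0.05 and 0.34, and no positive sample correlated best with its own number. The first principal component, which followed the hair score, held 56.3% of the variance. These correlations therefore cannot show whether samples of the same number share a batch or day. The replicate block over the 8 samples numbered 1 to 4 called 0 genes, with 2329 at an unadjusted p under 0.05. Named genes kept their direction in all settings.

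Lists called numbered 0 with an estimated correlation, fry and exact permutation, and in each fit that left out a sample, against 20 with the preset correlation and 18 with that and the hair score. List medians that changed sign were these, with the cause not tested. The sebaceous gland median (-0.003) was 0.0075 with DESeq2 size factors, 0.0257 with upper-quartile scaling, 0.0073 with DESeq2, 0.0732 with quality-weighted voom and 0.0218 on log2(TPM + 1). The cell cycle median (-0.03) was 0.0080 with upper-quartile scaling, 0.0037 with voom, 0.0274 on log2(TPM + 1), 0.20 with the hair score, 0.204 with muscle and adipocyte scores, 0.25 with 1 surrogate variable, 0.17 with the replicate block and 0.12 in its 8 samples without the block. The barrier median (0.18) was -0.109 with the hair score or 1 surrogate variable and -0.113 with muscle and adipocyte scores. The hair median (-2.27) was 0.162 with its own score and 0.164 with 1 surrogate variable. The mast cell median (0.12) was -0.228 with the hair score, -0.268 with 1 surrogate variable and -0.195 in the 8 samples. The nerve median (0.18) was -0.0625 with the hair score, -0.0937 with muscle and adipocyte scores and -0.0639 with 1 surrogate variable. With muscle and adipocyte scores, the adipocyte and muscle medians were -0.0050 and -0.0310, as that fit removes them. The p53 median (-0.05) was 0.0022 with 1 surrogate variable, and the dendritic cell median (0.06) was -0.0263 with the replicate block and -0.0312 without it. Leaving out each sample gave medians from -0.12 to 0.0784 for cell cycle, -0.0096 to 0.225 for dendritic cells, -0.0543 to 0.22 for erythroid, -0.0542 to 0.0046 for p53, -0.255 to 0.138 for sebaceous gland and -0.0195 to 0.85 for vitamin D. At this depth, genes below the filter on low counts could not be judged.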

Other observations

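Tests of correlations were chosen only after the scores were seen, and the genes named here were picked after their values were seen; none passed edgeR's test over all genes. Adipocyte genes had a median log2 fold change of 0.25, and 4 rose adjusted over the list alone, among them Adipoq (adiponectin) with 71.3 ± 13.8 CPM (SD, n = 4) against 43.7 ± 6.27 CPM (SD, n = 7). In the wound healing and growth factor list, with a median of 0.37, 4 members rose and 1 fell adjusted over the list alone. Fgf7, a fibroblast growth factor for keratinocytes, had 12.1 ± 3.86 against 6.31 ± 0.909 CPM, and Mmp3, a matrix protease, 97.1 ± 45.7 against 36.9 ± 14.2 CPM. In the immediate early and heat shock list, with a median of -0.27, 5 members fell adjusted over the list alone, among them Hspa1a with 73.1 ± 13.3 against 102 ± 10.3 CPM. All 3 lists were called with the preset correlation and had adjusted p = 0.426 with an estimated correlation. With the hair score as a covariate, the median was -0.07 for the immediate early and heat shock list. It was 0.21 for wound healing and growth factors and 0.22 for adipocytes. Jchain, the joining chain of secreted immunoglobulins, had 20.6 ± 13.2 against 3.96 ± 4.62 CPM.

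The medians of other lists were 0.20 for basal keratinocytes, 0.45 for activated keratinocytes, 0.12 for mast cells and basophils, 0.18 for nerve and Schwann cells, 0.06 for dendritic and Langerhans cells, 0.09 for erythroid and -0.05 for p53 and irradiation genes. Only the 2 keratinocyte lists were called with the preset correlation, with adjusted p = 0.426 and 0.616 with an estimated correlation. With the hair score as a covariate, their medians were 0.09 (basal) and 0.16 (activated). Leaving out each sample in turn gave mast cell medians from 4.7e-05 (without negative replicate 3) to 0.57 (without negative replicate 1) and nerve medians from 0.096 (without positive replicate 3) to 0.30 (without negative replicate 7), and took the activated keratinocyte median down to 0.28 (without positive replicate 1). The vitamin D list had a median of 0.51 while its test pointed down, and the cell cycle (-0.03) and sebaceous gland (-0.003) medians lay below 0 while their tests pointed up; all 3 had an adjusted p of 0.976 with an estimated correlation. The vitamin D target Cyp24a1 ranged from 23.3 to 282 CPM of all counts.

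A hypothesis was that the macrophage and interferon scores follow a shared inflammatory state of single samples. Over the 11 samples Pearson's r was 0.779 (permutation p = 0.00712) and Spearman's rho 0.482 (permutation p = 0.138), and without positive replicates 1 and 2 r was 0.082, so the relation rests on those samples. Macrophage and fibroblast scores had r = 0.850 and rho = 0.782 (permutation p = 0.00049 and 0.00629), and r = 0.682 without both. Macrophage and neutrophil scores had r = 0.854 and rho = 0.700 (permutation p = 0.00104 and 0.0203), and r = 0.578 without both. After Benjamini-Hochberg adjustment over these 3 relations, p was 0.00712, 0.00147 and 0.00156 for r and 0.138, 0.0189 and 0.0304 for rho, in the order given.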
